A study of Mus musculus with 8 samples.

How the data were processed

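Gastrocnemius RNA of 8 samples, 4 control and 4 ursolic acid, was measured on 1-colour arrays. Per the labels' protocols, total RNA was extracted with TRIzol, 50 ng of it was amplified by single-primer isothermal amplification, and the product was fragmented and labelled with biotin. The deposited values are on a log2 scale and were made with RMA, which corrects background, normalizes between arrays and summarises probes, with mm9 named as the genome build, per the submitters' processing notes. The RMA software and its version, the level at which probes were summarised and any filter on rows are not given in the sources used here. Neither is the base of the logarithm: base 2 was taken because natural logarithms would put the brightest values above what a 16-bit scanner can record. The design text speaks of levels set relative to untreated mice, but the deposited values are not ratios, so they were compared between groups as log2 values without further normalization. No signal above background is given per row.

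Of the 16755 rows, 14996 carry 1 gene symbol in the platform annotation, 1019 carry several and 740 carry none. Symbols were looked up by gene number in the RefSeq table of assembly GRCm38.p6, where 14941 matched, and no coordinates were used since the builds differ. Only rows with 1 symbol were named. They cover 14860 genes, and for the 135 genes with several rows the row with the highest mean stood for the gene in list tests.

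Groups were taken from the sample titles and the treatment field. Descriptions contradict these for 4 samples, in a pattern that follows odd and even sample numbers, so grouping by the description and other uses of it were run as alternatives. The labels do not say whether any mouse entered more than 1 pool. The p-values of single rows and of list scores measure the spread between these pooled samples. Camera compares the genes of a list with the other genes, so at its preset correlation its p-value is no measure of that spread. No arrays were identical.

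Each row was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend), with 4 arrays per group and no covariate, two-sided, with Benjamini-Hochberg adjustment over all rows at 0.05. Intervals are at 95%. Before the data were examined, 31 gene lists were written for muscle growth and atrophy, energy metabolism, fibre type, stress, the clock and the other cell types a muscle sample can hold. The 30 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry, each with Benjamini-Hochberg adjustment over the lists. A list's score is the mean over its genes of each value minus that gene's mean over the 8 arrays, compared between groups by a two-sided exact permutation test. "Adjusted over the list alone" means that the limma p-values of the list's members were adjusted among themselves.

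The genes named were fixed by a rule written before the data were examined. Up to 15 rises and 15 falls past the threshold were to be named, and, with fewer than 20 rows past it, those with the smallest p to a total of 20, leaving out predicted and olfactory or vomeronasal receptor genes. Added to these were 11 preset genes and up to 4 members of each list with the smallest p, 141 genes in all. Mrc1, Cd163, Ccr2, Adgre1, Csf1r, Cd3e, Cd3g, Cd79a, Ms4a1, Nfil3, Usp2, Bhlhe41 and Aldoa fall outside the rule and were named from their lists after their values were seen, as was Pmepa1.

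Alternatives set in advance were the replicate number as a block, centring on the median, quantile normalization, leaving out rows below the median level or below 8, a variance trend with robust moderation, no moderation, array weights, the first residual component as a covariate, each sample left out in turn, samples with concordant labels only, grouping by description, other thresholds and other list tests. The description as a covariate and fits within each description class were added after seeing the data. The methods were tested on simulated data for ursolic acid against control with 4 arrays each, 16755 rows drawn independently and 200 of them changed, in 20 simulations: limma recovered 63.2% of rows changed by 0.5 and 93.3% of those changed by 1 on the log2 scale, with 5.78% false among the calls. With the macrophage and leukocyte list raised by 0.3 among 14860 simulated genes, also drawn independently, camera at either correlation and fry each found it in 20 of 20 simulations, with 0 calls of unchanged lists among 30 by camera at its preset correlation. Independent genes cannot show false calls that come from correlation within a list. That correlation was estimated in the real arrays at 0.136 for the macrophage list and 0.431 for the fibroblast list. Depth is not defined for arrays, and their number limits the precision.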

Results

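Ursolic acid is a pentacyclic triterpenoid found in the waxy peel of apples and other fruit. The study asked how it changes mRNA levels in skeletal muscle of mice that eat it. Gastrocnemius, the large calf muscle, was taken from 12-week-old male C57BL/6 mice after 5 weeks on plain chow or on the same chow with 0.27% ursolic acid mixed in. Each sample was RNA pooled from 2 mice, and each group held 4 samples, so 8 arrays were compared. Every array gave a log2 expression value for the same 16755 rows of the chip. Array medians lay between 5.55 and 5.61, and single values ran from 1.74 to 13.2. The mean Spearman correlation with the other arrays was 0.977 for control sample 1 and 0.983 to 0.986 for the other 7 arrays, and the number of arrays limits the precision of each comparison. Groups follow the sample titles and the treatment field. The free-text description contradicts both for 4 of the 8 samples: it calls control samples 2 and 4 treated and ursolic acid samples 1 and 3 untreated.

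The genes with the smallest p between muscle from mice fed ursolic acid and control muscle mainly had higher values with ursolic acid. None of them passed correction over all rows in the main limma fit, with no variance trend and no array weights. Cyp2e1, a cytochrome P450 of foreign-compound metabolism, was 2.09-fold higher, at a log2 value of 7.30 ± 0.20 (SD, n = 4) against 6.24 ± 0.34 in control. Smox, which oxidises the polyamine spermine, was 1.75-fold higher, at 10.01 ± 0.25 against 9.21 ± 0.13. C3ar1, the receptor of the complement peptide C3a on myeloid cells, was 1.60-fold higher, and Ctss, a lysosomal protease of antigen-presenting cells, was 1.64-fold higher. Arntl, the gene of the clock activator BMAL1, was lower, at 5.67 ± 0.21 against 6.65 ± 0.30, or 0.507 of the control level.

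Of the 20 genes with the smallest p, 19 were higher and 1, Arntl, was lower. The groups did not overlap in any of the 20, which choosing genes by p favours. Their limma adjusted p-values ran from 0.0845 to 0.107. Beside Cyp2e1, the flavin monooxygenases Fmo1 and Fmo2, which also oxidise foreign compounds, had log2 differences of 0.47 ± 0.07 (SE) and 0.57 ± 0.09. Nceh1, a hydrolase of cholesterol esters, had a difference of 0.49 ± 0.07, and Slc7a2, a carrier of arginine and other cationic amino acids, had one of 0.78 ± 0.13. Also among the 20 were Tyrobp, a signalling adaptor of myeloid cells, at 0.69 ± 0.11; Cd74, the class II invariant chain, at 0.43 ± 0.07; Fyb, an adaptor of blood cells, at 0.46 ± 0.07; and Ms4a6d at 0.41 ± 0.07. The other higher genes were Calml4, Mmgt2, Tph1, Lrp2bp, Npnt, Jpt1 and Dpep1, with differences of 0.46 to 0.81.

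**Figure D1:**
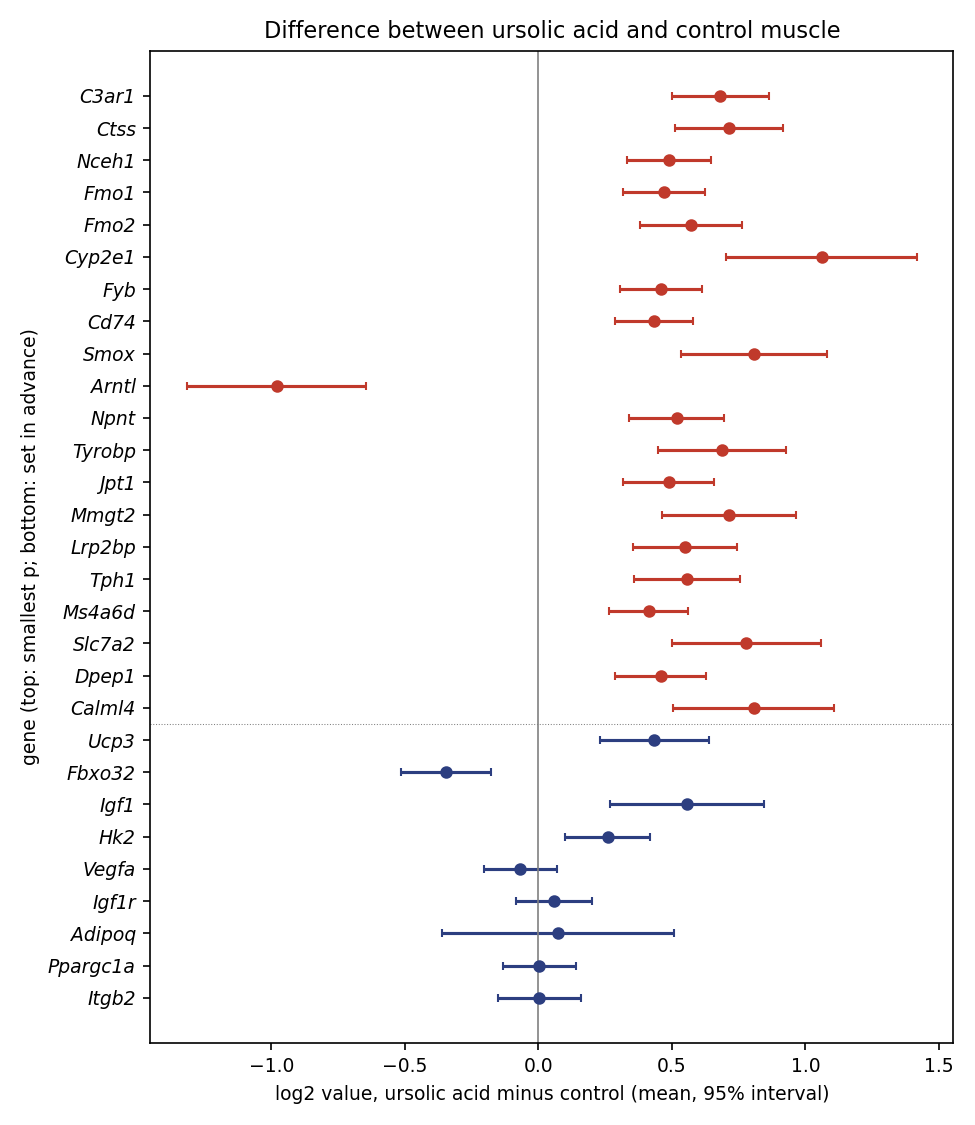
Log2 value in ursolic acid minus control muscle for the 20 genes with the smallest p (upper part) and for 9 genes set in advance (lower part), as the mean difference with its 95% interval from the limma fit on 4 arrays per group. Differences run from −0.98 for Arntl to 1.06 for Cyp2e1, and Smox stands in the upper part although it was also set in advance.

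By limma, 0 of the 16755 rows passed an adjusted p of 0.05, the smallest being 0.0845. At an adjusted p of 0.10, 20 rows passed, 19 higher and 1 lower. At an unadjusted p of 0.05, 1185 rows passed (683 higher, 502 lower) where 838 would by chance, and at 0.005, 211 passed (160 higher, 51 lower) where 83.8 would. The groups did not overlap in 752 rows, or 4.49%, where 2.86% would by chance with 4 against 4. The count at 0.05 depended on the model and on the rows tested: 12 rows passed with a variance trend and robust moderation, 23 with array weights, 27 with the rows below the median level left out, and 1 (Pmepa1, chosen after its value was seen) without moderation. Cyp2e1, Smox, C3ar1, Ctss and Arntl passed in each of these settings but the last. When the 8 arrays were regrouped by the free-text description, limma again gave 0 rows at an adjusted p of 0.05, with 2098 at an unadjusted p of 0.05.

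Among genes of muscle growth and energy use that were set in advance, Igf1, the growth factor that drives muscle hypertrophy, was 1.47-fold higher with ursolic acid, at 8.02 ± 0.26 (SD, n = 4) against 7.47 ± 0.16. Fbxo32, the ubiquitin ligase atrogin-1 that marks atrophying muscle, was lower, at 8.54 ± 0.13 against 8.88 ± 0.02, or 0.787 of the control level. Ucp3, a mitochondrial uncoupling protein of muscle, was 1.35-fold higher, and Hk2, the hexokinase that traps glucose in muscle, was 1.20-fold higher. In each of these genes all 4 ursolic acid arrays lay beyond all 4 control arrays. None passed over all rows, with limma adjusted p of 0.250 for Igf1, 0.210 for Fbxo32, 0.194 for Ucp3 and 0.388 for Hk2. When only the 1448 rows with a mean log2 value of at least 8 in a group were tested, 26 rows passed (21 higher, 5 lower), and Igf1 and Fbxo32 were among them. Igf1 reached 8 only in the ursolic acid group, so its own difference brought it into this test, and neither gene passed an adjusted p of 0.05 over the rows tested in any other setting run. The log2 differences of Igf1r, Vegfa and Adipoq were 0.06 ± 0.06 (SE), −0.07 ± 0.06 and 0.07 ± 0.20. Those of Itgb2 and Ppargc1a were both 0.00, with standard errors of 0.07 and 0.06. Trim63, the other gene set in advance, was not analysed here, since no row carried it as its only symbol.

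**Figure D2:**
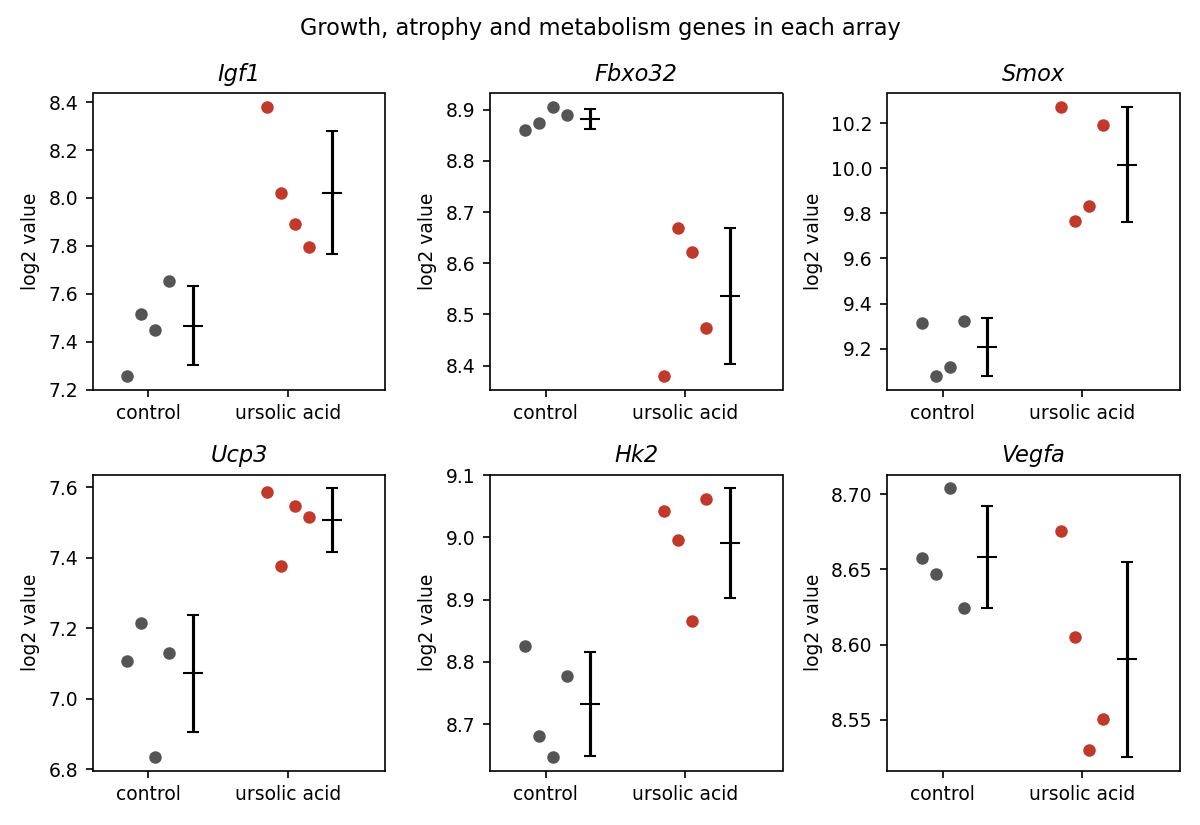
Log2 value of 6 genes set in advance in each of the 8 arrays (points), with the mean and SD of each group of 4 beside them. The vertical axes differ between panels and do not start at 0. Igf1, Smox, Ucp3 and Hk2 were higher and Fbxo32 lower in all 4 ursolic acid arrays than in any control array, and Vegfa overlapped.

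Markers of macrophages and other leukocytes rose as a list by camera and fry, though not by camera with an estimated correlation. The camera test gave the list an adjusted p of 9.79e-19 at its preset correlation between genes, and an adjusted p = 0.0848 with an estimated correlation. The first value compares genes and overstates what 4 against 4 pools can show. Regroupings of the arrays with equal numbers of control and ursolic acid on each side gave this list unadjusted camera p of 5.28e-05 to 0.974 at the preset correlation. The fry test gave an adjusted p of 0.0286. Of 27 measured members 25 were higher, with a median log2 difference of 0.30, and 16 rose when adjusted over the list alone, where limma passed 0 of them when adjusted over all genes. Mrc1 and Cd163, receptors of tissue macrophages, had differences of 0.65 and 0.42. Ccr2, the chemokine receptor of recruited monocytes, had one of 0.61, and H2-Aa, a class II chain, one of 0.60. The pan-macrophage markers Adgre1 and Csf1r had differences of 0.30 and 0.31. The 11 members that did not pass included the T and B cell markers Cd3e, Cd3g, Cd79a and Ms4a1, with differences of −0.05 to 0.15, and the integrin chain Itgb2. The list score was higher in all 4 ursolic acid arrays than in any control array (difference 0.30, exact permutation p = 0.0286, the smallest that 4 against 4 can give; 0.245 when adjusted over the 30 lists).

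Genes of fibroblasts and extracellular matrix also rose as a list by camera (adjusted p = 0.000497), though not with an estimated correlation (adjusted p = 0.556 with an estimated correlation). Of 27 measured members 20 were higher, with a median difference of 0.08, and only Lum, the collagen-binding proteoglycan lumican, rose when adjusted over the list alone, by 0.61 ± 0.11 (SE). Postn, Mfap5 and Sparc, also matrix proteins, had differences of 0.48, 0.27 and 0.19. The collagens, 39 genes grouped by symbol stem in the scan of families below, had a median difference of −0.07. They were taken whatever their level in muscle, and at an unadjusted p of 0.05, 2 were higher and 1 lower. They did not pass camera there (adjusted p = 0.305). The list score was above every control in 3 of the 4 ursolic acid arrays and lowest of all 8 in ursolic acid sample 2, without which the adjusted p was 1.18e-09. Interferon-stimulated genes rose as a list by camera (adjusted p = 0.0185), though not with an estimated correlation (adjusted p = 0.252 with an estimated correlation). Of 19 measured members 15 were higher, with a median difference of 0.09, and no member passed when adjusted over the list alone or at an unadjusted p of 0.05. Psmb9, an immunoproteasome subunit, and Gbp2 and Gbp3, interferon-induced GTPases, had differences of 0.17, 0.18 and 0.22. The call was also lost without control sample 4 (0.0767) or ursolic acid sample 1 (0.0827). Neither the fibroblast nor the interferon list passed by fry (0.442 and 0.0581), with rows below the median level left out (0.0632 and 0.283) or in samples with concordant labels (0.178 for each). The fibroblast call was lost in samples described as treated (0.125) and the interferon call in those described as untreated (0.213), settings of 4 arrays each. There the fibroblast scores overlapped, at −0.111 and 0.171 with ursolic acid against −0.106 and −0.010 in control. The interferon scores did not, at 0.083 and 0.018 against −0.031 and −0.046. The macrophage score was also higher, by 0.30, and whether either list followed it was not tested. Among the ursolic acid arrays, sample 3 had the highest macrophage score (0.249) and the lowest interferon score (0.018). Sample 2 had the lowest macrophage score (0.034) and the lowest fibroblast score (−0.111).

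**Figure D3:**
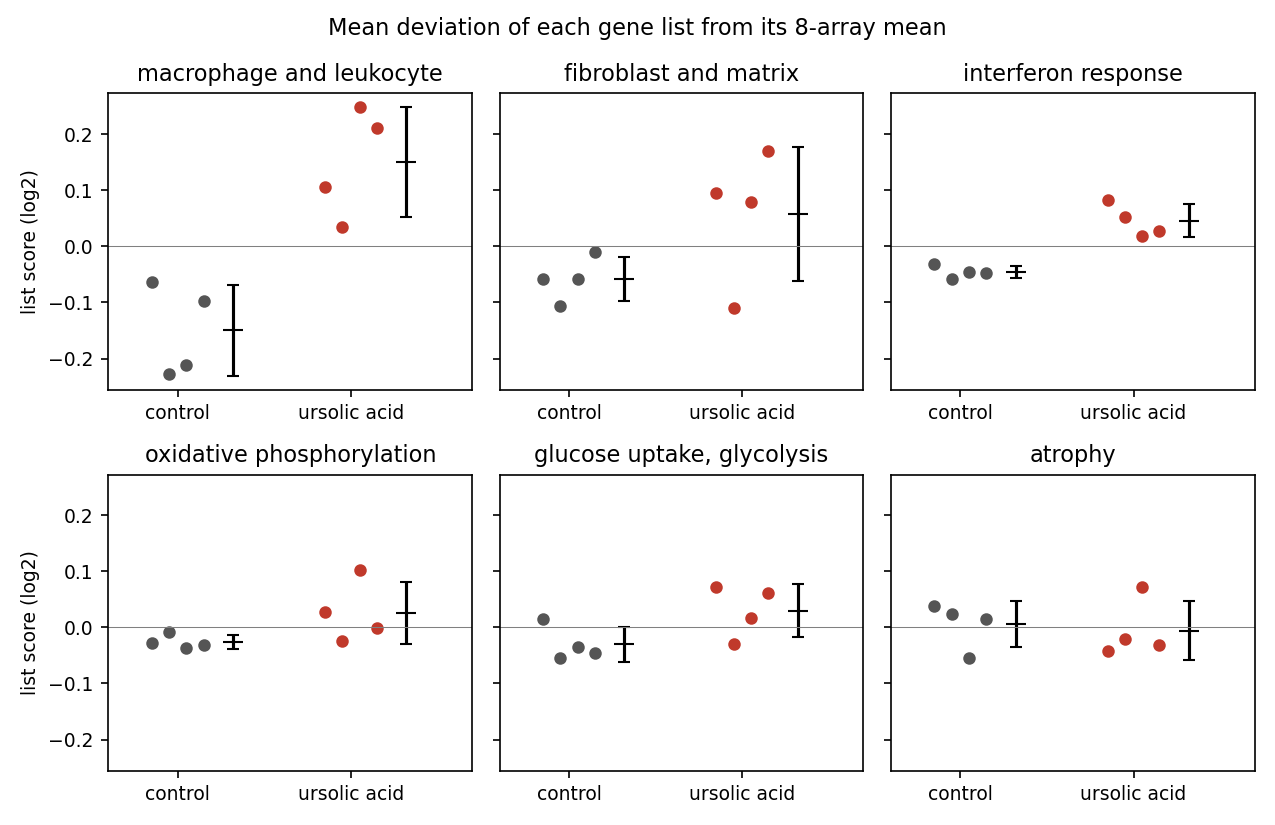
Score of 6 gene lists in each of the 8 arrays (points), as the mean over the list of each gene's log2 value minus its mean over the 8 arrays, with the group mean and SD beside the points. The macrophage and interferon scores separate the groups, the fibroblast score of ursolic acid sample 2 is −0.11, and the atrophy scores of the groups overlap.

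On the side of energy metabolism, the list written for glucose uptake and glycolysis rose by camera (adjusted p = 0.0185), though not with an estimated correlation (adjusted p = 0.556 with an estimated correlation). Of 19 measured members 12 were higher and 7 lower, with a median difference of 0.06. Fbp2, the muscle fructose bisphosphatase, and Hk2 rose when adjusted over the list alone, by 0.37 and 0.26. Gbe1, which branches glycogen, and Pdha1, a subunit of pyruvate dehydrogenase, had differences of 0.21 and 0.18 that did not pass, and Aldoa, a glycolytic aldolase, had one of −0.27. Of the members named here only Hk2 and Aldoa are enzymes of glycolysis, and they differed in direction. Subunits of the respiratory chain and ATP synthase rose as a list by camera (adjusted p = 0.0058), though again not with an estimated correlation (adjusted p = 0.556 with an estimated correlation). Of these 41 genes 32 were higher, with a median difference of only 0.04, and 0 passed when adjusted over the list alone, with 3 at an unadjusted p of 0.05: Cox7b, Cox7a2 and Ndufs4. Over all rows, differences correlated with the mean level at 0.153, so brighter rows tended to be higher. The median control level was 10.2 for this list and 8.89 for the glucose list, against 5.63 over all genes. Whether this trend with level gives the rise of either list was not tested. Neither list passed by fry (0.405 for the respiratory chain, 0.393 for glucose), and both calls were lost under quantile normalization (0.156 and 0.0723), with rows below the median level left out (0.0913 and 0.0837) or below 8 left out (0.281 and 0.136), in samples with concordant labels (0.424 and 0.511) and in samples described as treated (0.695 and 0.0508), and the glucose call in those described as untreated (0.225). The respiratory chain call was also lost without ursolic acid sample 3 (0.192), and the glucose call without control sample 2 (0.107), control sample 4 (0.0767), ursolic acid sample 1 (0.128) or ursolic acid sample 4 (0.0649). The respiratory chain score was 0.102 in ursolic acid sample 3 and −0.025 to 0.027 in the other ursolic acid samples. Control scores ran from −0.036 to −0.008. In samples described as treated the respiratory chain scores overlapped, at −0.025 and −0.001 with ursolic acid against −0.008 and −0.031 in control. The glucose scores there did not, at −0.030 and 0.061 against −0.055 and −0.045.

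Clock genes moved both ways. When adjusted over the list alone, 7 of 16 measured members passed, 4 higher and 3 lower. Arntl, its partner Npas2, and Nfil3, a repressor of clock outputs, fell by 0.98, 0.20 and 0.27 on the log2 scale. Dbp, a transcription factor driven by the clock, rose by 0.56, Usp2 by 0.31, Tspan4 by 0.28 and Bhlhe41, a repressor in the clock loop, by 0.21. The list as a whole did not pass camera (adjusted p = 0.11), while fry's test for change in either direction gave an adjusted p of 0.00168. Hour of harvest is not given in the sources used here.

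**Figure D4:**
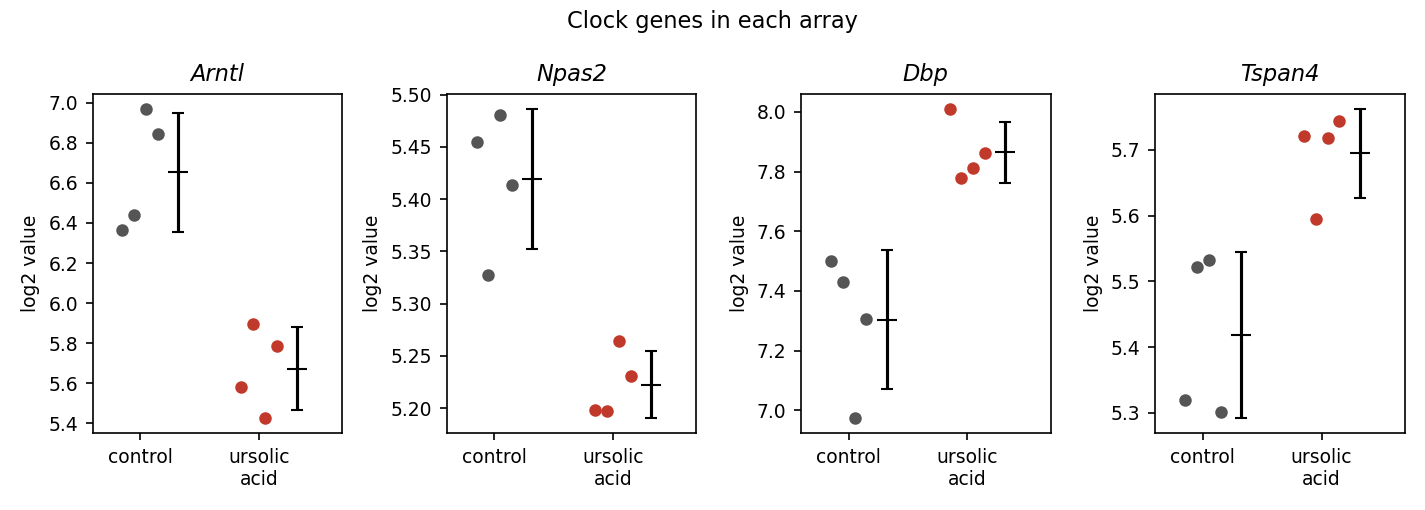
Log2 values of the 4 clock genes with the smallest p in each of the 8 arrays (points), with the mean and SD of each group of 4 beside them. The vertical axes differ between panels and do not start at 0. Arntl and Npas2 were lower and Dbp and Tspan4 higher in every ursolic acid array than in any control array.

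The atrophy list did not move as a whole (camera adjusted p = 0.955; 14 of 28 members higher), and only Fbxo32 fell when adjusted over the list alone, by 0.35 on the log2 scale. Mstn, the growth inhibitor myostatin, had a difference of 0.26, and Cdkn1a, the cell cycle inhibitor p21, one of −0.36. In the list of IGF-I, insulin and Akt signalling (adjusted p = 0.731), Igf1 was the only one of 28 members to pass over the list alone, rising by 0.56. Pik3r1, a regulatory subunit of PI3-kinase, and Deptor, an mTOR inhibitor, had differences of 0.30 each. By the same adjustment, Smox alone rose among 10 polyamine genes, by 0.81, and Ucp3 alone among 27 genes of fatty acid oxidation, by 0.43. Of 12 heat shock genes, Hspb8 and Hsph1 rose by 0.32 and 0.30 and the inducible Hspa1a fell by 0.60. Of 22 immediate early genes, Nr4a3 fell by 0.42, and Egr1, which did not pass, had a difference of −0.25. The polyamine, fatty acid oxidation, heat shock and immediate early lists had camera adjusted p of 0.426, 0.955, 0.426 and 0.438. By fry's test for change in either direction, 8 lists passed: atrophy, IGF-I and insulin signalling, glucose uptake, polyamines, targets of NRF2 and xenobiotic response, heat shock, clock, and macrophages and leukocytes.

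The score of cholesterol synthesis was lower in all 4 ursolic acid arrays than in any control array (difference −0.09, exact permutation p = 0.0286, the smallest possible; 0.245 when adjusted over the 30 lists), and the list did not pass camera (adjusted p = 0.11). Of its 18 members 14 were lower, among them the regulator Srebf2 (−0.26) and the synthase Fdps (−0.43). Markers of adipocytes (0.148), pericytes and smooth muscle (0.247), endothelium (0.257), tendon (0.379) and Schwann cells (0.99) did not pass camera either, the values being adjusted p. The same held for slow fibre genes (0.955), fast fibre genes (0.629), genes of denervation and regeneration (0.955), mitochondrial biogenesis and the citric acid cycle (0.668), lipogenesis (0.955) and brown fat (0.955). It held too for NRF2 targets (0.594), the ATF4 response (0.296), glucocorticoid targets (0.438), angiogenic factors (0.955), the cell cycle (0.99) and ribosomal proteins (0.955). Red cell genes had 3 measured members, Alas2, Bpgm and Slc4a1, and were not tested as a list; their differences were −0.02, 0.02 and 0.01. Sln, a regulator of the calcium pump, and Csrp3, a muscle LIM protein, in the slow fibre list, had differences of 0.34 and −0.35 that did not pass. The list median, mean and test differed in sign for atrophy, fatty acid oxidation, fast fibre, denervation, brown fat, polyamine, heat shock, nerve and ribosomal genes, all with medians under 0.04 in size.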

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

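The test of receptor rows and the count of labelings below were chosen only after the result was seen. In 352 sets of 4 samples (a gene, a list score or an array measure within a group), 22 had 1 sample far from the other 3, where chance gives about 1 in 20. Each value given for them is the gap to the nearest other sample divided by the range of the group.

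Control sample 1 stood apart in 5 of them. Its mean correlation with the other arrays, 0.977, lay below 0.985 to 0.986 in the other controls (0.921), and its ribosomal protein score was the lowest control score (0.890). Its Thbs1 value, 7.12 against 6.22 to 6.32, was high (0.883), as was its Sesn2 value (0.841), and its Mylk value was low (0.947). The first principal component, 28.3% of the variance, placed control sample 1 at −25.6 and the other arrays between −5.13 and 10.8. The 4 arrays described as treated lay between 2.07 and 10.8 and the 4 described as untreated between −25.6 and 0.96. The first component thus parts the arrays by the contradictory descriptions and not by the titles. The second component, 15.3% of the variance, parts them by the titles. Controls lay between −12.01 and 2.298 on it, and ursolic acid arrays between 2.888 and 11.02. Control sample 1 and ursolic acid sample 2 lay close together there, and chance was not tested for this parting. Olfactory, vomeronasal and taste receptor rows, which muscle hardly expresses, were not clearly more frequent among the rows that differed most between the description classes. They made up 6.6% of the 500 rows with the smallest p and 5.91% of all rows (Fisher's exact p = 0.50). Other effects of signal level were not tested, and differences between the classes correlated with the mean level at 0.212. Control sample 1 alone as the source and a batch that followed odd and even sample numbers cannot be told apart. Without control sample 1 the first component still put 6 of the 7 remaining arrays on their side at the best dividing point, but 14 of the 35 ways to label 7 arrays do as well, so 7 arrays are too few to decide. Rows at an unadjusted p of 0.005 between the description classes numbered 227 with control sample 1 and 128 without it. No biological explanation was tested.

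Among other list scores, control sample 4 was low for slow fibre genes (0.867), ursolic acid sample 1 was high for polyamine genes (0.901), and ursolic acid sample 3 was high for the cell cycle (0.870). Ursolic acid sample 4 was high for cholesterol synthesis (0.867) and for pericytes and smooth muscle (0.864).

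Among named genes, ursolic acid sample 4 was high for Fmo2 (0.847) and Fyb (0.891), and ursolic acid sample 3 was low for Tph1 (0.839) and high for Slc4a1 (0.836). Ursolic acid sample 2 was low for Sesn2 (0.854), Rps3 (0.890), Azin2 (0.884) and Kera (0.842), and ursolic acid sample 1 was low for Drp2 (0.830). Control sample 4 was high for Mstn (0.841) and low for Tie1 (0.892), and control sample 3 was low for Ndufs4 (0.845).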

How the results depend on the processing

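The fits with the description as a covariate and within each description class were chosen only after the data were seen. With the replicate number as a replicate block, limma gave 0 rows (227 at an unadjusted p of 0.005) and 5 gene lists, the same 5 as without it. Whether the numbers pair the samples could not be decided from 4 numbers. Deviations of same-numbered samples correlated at 0.133, 0.083, 0.018 and 0.186, and in 2 of the 4 numbers another number correlated better. Of 2830 values of named genes under alternatives, 2774 stayed on their side of the threshold, 56 passed it and 0 turned direction past it. Signs changed in 37 values of 15 of the 141 genes, none of them among the 20 with the smallest p.

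The count of rows at an adjusted p of 0.05 moved from 0 to 27 (24 higher, 3 lower) with rows below the median level left out, 26 with rows below 8 left out, 12 with trend and robust moderation, 1 without moderation and 23 with array weights. It was 20 at an adjusted p of 0.10, 211 at an unadjusted p of 0.005 and 30 at the latter with a level of at least 8 (26 higher, 4 lower). It stayed at 0 under centring, quantile normalization, the residual component, each use of the description and with each sample left out (93 to 319 rows at an unadjusted p of 0.005). With fewer rows tested the adjustment is milder. For the other settings the cause was not tested.

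The count of 5 lists was 3 under quantile normalization, 1 with rows below the median level left out, 1 with rows below 8 left out (fibroblast and matrix, of 13 testable), 1 in samples with concordant labels, 0 by description (2 at an unadjusted p of 0.05), 3 in samples described as treated, 0 by camera with an estimated correlation (2 unadjusted) and 1 by fry (macrophage and leukocyte). With 1 sample left out it was 3 to 7, the 7 being without control sample 1, where adipocyte and glucocorticoid lists also passed. Adipocyte markers passed too with array weights and in samples described as treated, cholesterol synthesis in samples described as untreated and without ursolic acid sample 4, and pericytes and smooth muscle without that sample. The adjusted p of the list of glucose uptake was 0.0723 under quantile normalization, 0.0837 and 0.136 with rows below the median level or below 8 left out, 0.511 with concordant labels, 0.225 and 0.0508 in samples described as untreated and treated, 0.556 with an estimated correlation and 0.393 by fry (0.00451 to 0.128 with 1 sample left out). For oxidative phosphorylation it was 0.156 under quantile normalization, 0.0913 and 0.281 with those rows left out, 0.424 with concordant labels, 0.695 in samples described as treated, 0.556 with an estimated correlation and 0.405 by fry (0.000367 to 0.192). For fibroblasts and matrix it was 0.0632 with rows below the median level left out, 0.178 with concordant labels, 0.125 in samples described as treated, 0.556 with an estimated correlation and 0.442 by fry (1.18e-09 to 0.0277). For interferon it was 0.283 with rows below the median level left out, 0.178 with concordant labels, 0.213 in samples described as untreated, 0.252 with an estimated correlation and 0.0581 by fry (0.0137 to 0.0827). The macrophage list lost its call with an estimated correlation (0.0848), was not testable with rows below 8 left out, and stayed at 1.84e-21 to 2.24e-13 with 1 sample left out. Grouped by description it was at 0.888. Each description class holds equal numbers of both title groups, so a difference by title cancels in that grouping for every list. Its count of 0 lists therefore says nothing against the calls by title. Settings with concordant labels or 1 description class hold 4 arrays. Among samples with concordant labels the groups also part wholly by description, and control sample 1 is one of them. Camera without moderation was not run, as it always moderates. Signal over background is not known per row, so a floor on dim rows could not be set from the data.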

Other observations

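The tests of the description classes and of adipose tissue for the macrophage genes, the scores with samples left out, the test of harvest hour for the clock genes, the splits for counts of rows and the scan of gene families with its fit beside the description were chosen only after the result was seen.

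Some genes outside the fixed lists were also higher with ursolic acid, without passing over all rows in the main limma fit. Alox5ap, the activating protein of leukotriene synthesis in myeloid cells, was higher by 0.58 ± 0.10 on the log2 scale (SE, limma adjusted p = 0.115). Casp4, an inflammatory caspase, was higher by 0.38 ± 0.09 (adjusted p = 0.267), and the interferon-induced Ifi27l2a by 0.56 ± 0.17 (adjusted p = 0.458). Socs2, which restrains growth hormone signalling, was higher by 0.62 ± 0.12 (adjusted p = 0.188). With array weights, Alox5ap and Socs2 passed over all rows (limma adjusted p = 0.0469 for each). All 4 were picked after their values were seen.

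In a scan of 240 gene families grouped by the stem of their symbols, camera at its preset correlation called 12, 9 up and 3 down, and with an estimated correlation 0 (4 at an unadjusted p of 0.05; adjusted p = 0.965 for each of the 12). By fry 1 family passed, the integrin alpha chains (Itga, 9 members, median −0.06). Among the 12, proteins of the large mitochondrial ribosomal subunit (Mrpl, 43 genes) were higher by a median of 0.08, with 7 members higher at an unadjusted p of 0.05, among them Mrpl47 at 0.25 and Mrpl40 at 0.23. The Ifi family of interferon-induced genes (8 members, median 0.18) and the Cox family of cytochrome oxidase subunits and assembly factors (16 members, median 0.04) were also up. The Sox genes (20 genes, median −0.09), keratins (Krt, 36 genes, median −0.09) and cadherins (Cdh, 19 genes, median −0.09) were down. Over all rows, differences correlated with the mean level at 0.153 by title and 0.212 by description. Whether this trend with level gives the family differences was not tested. Chance cannot be excluded for the count: 3 of the 35 splits of the arrays gave as many families, the highest other being the split by description with 26. With the description as a covariate 4 families passed, all among the 12.

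The rise of macrophage and leukocyte markers did not come from a single description class, since the median difference was 0.288 in one class and 0.325 in the other. Each title group holds equal numbers of both classes, so a uniform shift between the classes cancels in this comparison whatever the data. Lymph node tissue in the samples would bring B and T cell transcripts, but their score was higher by only 0.0134 against 0.30 for the macrophage list (exact permutation p of the difference 0.0286, the smallest possible; 0.0571 without control sample 3 or ursolic acid sample 1, 3 or 4, where the lymphocyte score differed by −0.04 to 0.05). Of the 21 measured lymphocyte genes 4 were also in the macrophage list and 3 lay above the median gene of control muscle. In the macrophage list 13 of 27 lay above it. The median control level was 4.69 for the lymphocyte genes and 5.56 for the macrophage list, so the scores compare genes of unlike level. Adipose tissue stays open. The score of 8 adipocyte genes, picked after the adipocyte list was seen, was higher by 0.0558 (exact permutation p of the difference from the macrophage score 0.0286), but with the whole adipocyte list this p was 0.0571. Without control sample 1 the score of the 8 genes was higher by 0.10 and that p was 0.0571, and the adipocyte list passed camera there, with array weights and in samples described as treated. Adipoq had a difference of 0.55 in samples described as treated and −0.41 in those described as untreated, where the macrophage score was higher by 0.29 and 0.31. A hypothesis also left open is that the diet may change the number or the state of myeloid cells in muscle, which bulk RNA does not tell apart; counting these cells in muscle sections or by flow cytometry, with RNA from sorted cells, would decide it.

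When clock genes were sorted by phase, 10 in the phase of Dbp had a mean difference of 0.22 and 5 in the phase of Arntl one of −0.32. The gap between them was 0.543. It describes the pattern and is no separate test of it, since the genes were sorted after Arntl and Dbp had been seen to differ in opposite directions. The gap was 0.460 and 0.626 in the description classes, so it was present in both. A uniform shift between the classes would cancel here too. A different hour of harvest between the groups and a change of the clock by the diet could each give this pattern, and they cannot be told apart because no harvest hour is given in the sources used here.

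The 8 arrays can be split into 4 and 4 in 35 ways. At an adjusted p of 0.10 only the real split, 1 of 35, gave as many as 20 rows, and the highest other gave 1. As this is the smallest share that 35 splits can give and 1 of 5 counts compared in this way, it would not pass an adjustment over the 5, and chance is not excluded over them together. At an adjusted p of 0.05 the real count by limma was 0 (1185 at an unadjusted p of 0.05), so all 35 splits reach it whatever the data, and the comparison says nothing about chance; the highest other was 1. At an unadjusted p of 0.005, 3 splits gave as many as the real 211, the highest other giving 239, and one of the 3 was the split by description with 227, so chance cannot be excluded there. With the description as a covariate the real count was 251. For the 5 gene lists called by camera chance cannot be excluded either, as 11 splits gave as many, up to 8.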
